A study of Caenorhabditis elegans with 22 samples.

How the data were processed

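RNA was extracted with Trizol from worms grown on NGM plates with OP50 bacteria, per the labels' protocols. Synchronised L1 larvae were grown for 44 h at 25 °C (young adults) or for 48 h at 20 °C (L4 larvae), and embryos were taken by hypochlorite treatment of adults, per the same protocols. Libraries were prepared with the TruSeq Stranded Total RNA kit, per the labels' protocols. Per the submitters' processing notes, adapters were trimmed with cutadapt 2.7, reads were aligned with HISAT2 2.1.0, reads per gene were counted with featureCounts 1.6.4 of the Subread package, and the authors compared groups with DESeq2 1.22.1. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The values analysed are the raw count per gene and library that the authors deposited. No value was excluded and every count column was matched to a library by its label.

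Gene symbols and coordinates come from Ensembl WBcel235 release 115. Of the 46932 gene IDs, 44108 (94%) had a symbol and 13 were not in that annotation. Several IDs share a symbol with another ID, mostly among histones and repeated RNA genes, so no such gene is named by symbol.

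Counts were tested in R 4.3.3 with edgeR 4.0.16, fitting each stage alone and comparing mutant with wild type. Genes were kept by filterByExpr at its default settings, libraries were scaled by TMM, and the quasi-likelihood F test was adjusted by the Benjamini-Hochberg method at 0.05. CPM values are scaled by TMM, and log2 CPM uses a prior count of 2. Standard errors come from the F statistic and 95% intervals from the t distribution. A second fit of all 22 libraries tested whether the genotype effect differs between the 3 stages. The labels do not state whether replicates are separate cultures, so the p-values measure only the spread between these samples. Replicate pairs within a group differed by more than counting noise, with a chi-square per degree of freedom from 23.3 to 258 over 30 pairs. Each genotype is 1 strain, so genotype and strain background cannot be told apart.

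A set of 28 gene lists was written before the data were examined, 7 of them by symbol prefix and the others by symbol. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and adjusted within each stage. The preset assumes a small correlation between the genes of a list, so its calls are given beside those with an estimated correlation. The fixed microRNA gene list matched 8 symbols and the mitochondrial genome list 0, too few to test, so lists by annotated biotype and by chromosome were added after the data were seen. Example members were taken in the order in which each list was written. Named genes are the edited genes, the 5 genes with the smallest p at each stage, targets in written order and genes picked out by the other tests named here.

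Apart from what is said to be added, the choices of fit, filter, test, lists and alternatives were made before the data were examined. The alternatives were DESeq2 1.42.0 size factors in edgeR, no low-count filter, DESeq2's own test, ribosomal RNA and mitochondrial genes removed, the replicate number as a block, 1 fit of all 22 libraries, a 2-fold minimum, an estimated correlation in camera, the rotation test fry, and each library left out in turn. Added after the data were seen were a single genotype effect over the 3 stages, the comparisons between wild-type stages, a principal component covariate built within groups (which changes the spread and, to a lesser extent, fold changes, as for *cls-3* in L4 larvae, from -1.62 to -1.82), removal of both first embryo libraries, and leaving out each library for the added lists. Labels were also regrouped, by every split of the libraries of a stage or by 99 random relabellings within stages. Figures were drawn with matplotlib 3.10.9.

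The scripts were tested on simulated data, with counts drawn from the means, depths and gene-wise spread of the real libraries and genes changed by known folds. In each stage fit 200 genes were changed, and genes were drawn independently of each other. Variation that many genes share between the real libraries was left out. Recovery of a few changed genes in the real data can therefore be lower. In the fits of 15172 simulated genes over the 3 stages, 93.0% of genes changed 4-fold were recovered by the single genotype effect and 74.5% by the interaction test. In the stage fits unchanged genes gave 3, 2 and 3 false calls among 12298, 12277 and 12133 simulated genes of young adults, L4 larvae and embryos.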

Results

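Total RNA was sequenced from *Caenorhabditis elegans* of 2 genotypes at 3 stages. The mutant, *alg-1(AEDH); alg-2(AEDH)*, carries an alanine in place of an aspartate in the catalytic tetrad of both major microRNA Argonautes, the proteins that bind microRNAs and repress their target transcripts. The wild type was the N2 strain. There were 4 mutant and 4 wild-type libraries of young adults, 3 and 3 of L4 larvae (the last larval stage), and 4 and 4 of mixed embryos. Each library held between 12.4 and 19 M counts (M, 1e+06 counts) over 46932 genes. Mean totals were 17.7 ± 0.918 M (SD, n = 4) in mutant and 18 ± 0.598 M (n = 4) in wild-type young adults, 17.7 ± 1.15 and 18.1 ± 0.864 M (n = 3 each) in L4 larvae, and 15.6 ± 2.39 and 16 ± 0.855 M (n = 4 each) in embryos. Ribosomal RNA took 17 ± 6.98% of counts in mutant L4 larvae, from 9.42% to 23.2%, against 12.8 ± 1.83% in wild type. In young adults it took 11.2 ± 0.957% and 10.1 ± 0.75%, and in embryos 14.3 ± 4.36% and 13.7 ± 1.91%. The comparisons ask which transcripts differ in level when the catalytic residues needed for target slicing are altered.

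Transcripts of both edited genes were present in every group, and no difference between mutant and wild type passed the test. *alg-1* (WBGene00000105, chromosome X, 13949110 to 13956261) stood at 59.2 ± 23.5 CPM (counts per 1e+06 counts; SD, n = 4) in mutant and 48.7 ± 14.8 CPM in wild-type young adults, at 158 ± 64.3 and 121 ± 44.6 CPM (n = 3) in L4 larvae, and at 400 ± 33.9 and 417 ± 104.4 CPM (n = 4) in embryos. *alg-2* (WBGene00000106, chromosome II, 873212 to 879885) stood at 103 ± 42.2 and 85.9 ± 28.6 CPM, 122 ± 39.0 and 78.3 ± 19.7 CPM, and 758 ± 198 and 670 ± 145 CPM in the same order. The log2 fold changes of *alg-1* were 0.28, 0.38 and -0.06, with standard errors of 0.31, 0.40 and 0.18, and those of *alg-2* were 0.26, 0.64 and 0.18, with standard errors of 0.33, 0.31 and 0.22. None passed edgeR's test. In young adults both values went to about 0 without mutant replicate 1 (-0.02 and -0.01), and *alg-1* in embryos changed sign or went to 0 without wild-type replicate 2 (0.08), wild-type replicate 3 (0.00) or mutant replicate 3 (0.01). Leaving out single libraries gave 0.21 to 0.74 for *alg-1* and 0.44 to 0.87 for *alg-2* in L4 larvae, and 0.08 to 0.36 for *alg-2* in embryos. A substitution of a residue leaves the transcript in place, so these levels do not check the genotype labels.

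*gpap-1* and *cls-3* had lower levels in every mutant library than in every wild-type library at each stage. *gpap-1* (WBGene00012390, chromosome I, 13751234 to 13756354, protein coding) stood at 4.17 ± 0.735 CPM in mutant and 9.64 ± 1.65 CPM in wild-type young adults, at 2.15 ± 1.06 and 5.60 ± 0.174 CPM in L4 larvae, and at 4.85 ± 0.973 and 13.1 ± 1.82 CPM in embryos. Its log2 fold changes were -1.21, -1.36 and -1.42, with standard errors of 0.24, 0.37 and 0.19. *cls-3* (WBGene00013847, chromosome III, 9186558 to 9191109), of the CLASP family of microtubule-binding proteins, stood at 6.5 ± 2.97 and 28.2 ± 5.83 CPM in young adults, 3.12 ± 2.36 and 9.73 ± 3.13 CPM in L4 larvae, and 42.7 ± 6.38 and 63.3 ± 8.57 CPM in embryos. Its log2 fold changes were -2.12, -1.62 and -0.57, with standard errors of 0.33, 0.54 and 0.15. Its paralogs *cls-1* and *cls-2* had log2 fold changes between -0.07 and 0.18. In a fit of all 22 libraries with a single genotype effect, added after the data were seen, *gpap-1* fell by 1.34 on the log2 scale (95% interval -1.65 to -1.03, a 2.53-fold lower level, adjusted p = 0.000116 by edgeR), the only gene of 15433 to pass. *cls-3* had a log2 fold change of -1.42 there and missed the threshold (adjusted p = 0.0776 by edgeR), but passed with DESeq2 (adjusted p = 7.17e-05, from 7.17e-05 to 0.272 over the alternatives). The adjusted p of *gpap-1* ran from 1.74e-19 to 0.000545 over its alternatives. Stage by stage neither gene passed edgeR's test in the main fits, though some alternatives called *gpap-1* in embryos. In L4 larvae *cls-3* was called only with the principal component covariate, added after the data were seen. That covariate is fitted to the spread of the same libraries, so its call is weak support. With DESeq2 both passed in young adults (adjusted p = 0.0116 for *gpap-1*, from 0.0116 to 1 over the alternatives, and 1.46e-05 for *cls-3*, from 1.46e-05 to 1) and *gpap-1* in embryos (adjusted p = 1.81e-07, from 6.34e-08 to 1). *cls-3* lies within ZC84.7 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so reads of this pair cannot be assigned to strands with certainty. Over all 22 libraries ZC84.7 holds 88 counts against 10383 for *cls-3*.

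**Figure D1:**
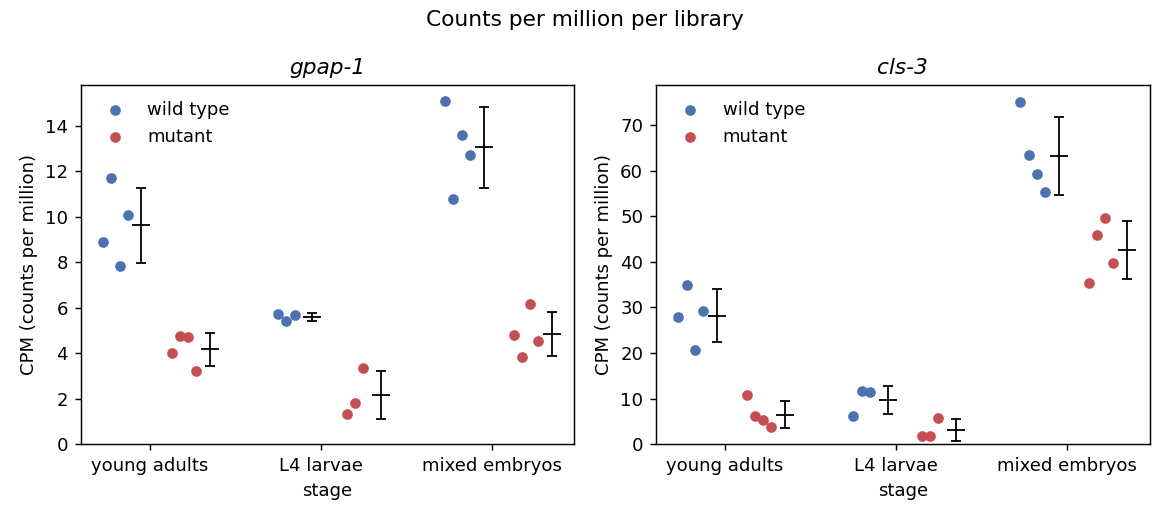
CPM of *gpap-1* and *cls-3* in each of the 22 libraries by stage (blue, wild type; red, mutant), with the mean and SD of each group beside its points. At each stage all mutant points lie below all wild-type points.

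No tested member of the fixed list of 25 known microRNA targets differed in level between the genotypes by test. Other targets were not gathered, and whether each member is a direct target was not tested. In embryos, where intervals were narrowest, the log2 fold changes of *lin-14*, *lin-28*, *lin-41*, *hbl-1*, *daf-12* and *let-60*, targets of the developmental timing microRNAs, were 0.00, -0.04, 0.13, -0.06, 0.10 and 0.12. The 95% intervals ran at most from -0.44 to 0.49. Whether the timing microRNAs act on these targets in embryos was not tested. The narrow embryo intervals therefore do not show that repression was kept. In L4 larvae the values were -0.28, -0.22, 0.21, -0.51, -0.27 and 0.54, and in young adults 0.26, -0.17, -0.06, 2.36, 0.19 and 0.22. The L4 intervals were wider, at most from -1.37 (*lin-14*) to 1.15 (*let-60*), and leave room for changes of that size. The 2.36 of *hbl-1* in young adults (interval -0.09 to 4.81) came from mutant replicate 1, which held 94.7 CPM against at most 7.49 CPM in the other libraries, and was -0.41 without it. No member of the list passed edgeR's test at any stage, over all genes or adjusted over the list alone. As a list, 18 of 23 tested members were higher in mutant young adults, with a median of 0.17 (adjusted p = 0.0551 by camera, 0.749 with an estimated correlation). Of 24 tested in L4 larvae 11 were higher, with a median of -0.15 while camera's direction was up (adjusted p = 0.89). Of 24 tested in embryos 9 were higher (median 0.00, adjusted p = 0.957 by camera). The 21 microRNA biogenesis and silencing factors had medians of 0.00, 0.18 and 0.03 in the 3 stages, and camera called none of these shifts (adjusted p = 0.626, 0.303 and 0.158).

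**Figure D2:**
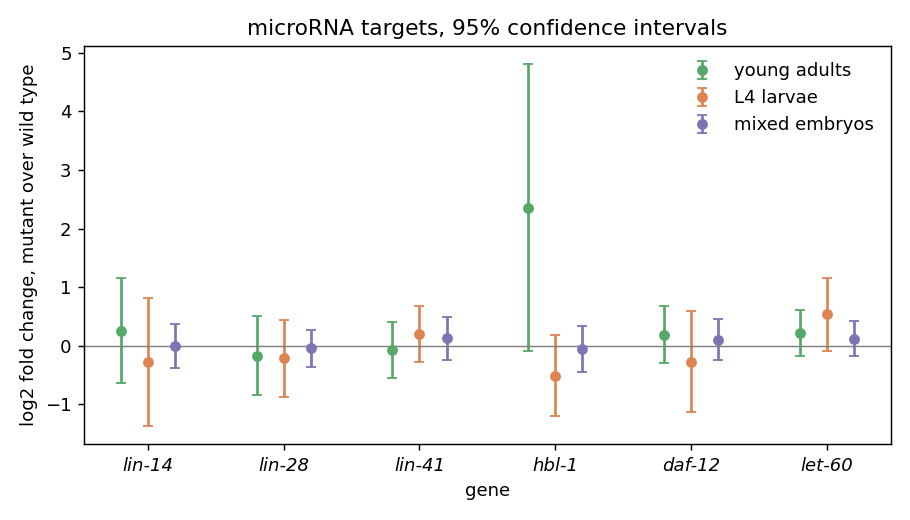
Log2 fold change, mutant over wild type, of 6 microRNA targets in young adults, L4 larvae and mixed embryos, with bars for 95% confidence intervals. Every interval includes 0, and the widest is that of *hbl-1* in young adults.

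In young adults no gene passed edgeR's test. Of 12561 genes tested, 0 passed at an adjusted p of 0.05. An unadjusted p under 0.05 was found for 145 (1.15%, 106 higher and 39 lower in the mutant). This is below the share of 0.05 that a calibrated test gives if no gene differs. The test was therefore conservative here, and the lack of calls is weak evidence of no change. DESeq2 called 2, *cls-3* and *gpap-1*. Besides these, the smallest unadjusted p belonged to *srh-71*, of a chemoreceptor family (log2 fold change -1.77; 0.306 ± 0.0352 against 1.06 ± 0.381 CPM), *col-40*, a cuticle collagen (3.32; 2.28 ± 2.49 against 0.22 ± 0.123 CPM), and K02G10.5 (1.39; 1.62 ± 0.473 against 0.614 ± 0.113 CPM), none of which passed. *col-40* was highest in mutant replicate 1, at 5.93 CPM against at most 1.78 CPM elsewhere. For 7003 genes (55.8%) the 95% interval of the fold change lay within 2-fold of no change. On simulated counts of the same depth and gene-wise spread, with 200 changed genes, the test recovered 57.1% of genes changed 4-fold and 6.15% of those changed 2-fold.

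In mutant young adults cuticle and moulting genes had higher medians and oocyte and early embryo genes slightly lower ones, in calls that camera made with its preset correlation and lost with an estimated one (adjusted p = 0.537 for each of these lists with an estimated correlation). Of 112 tested cuticle collagens 107 were higher, with a median log2 fold change of 1.03 (adjusted p = 6.95e-17 by camera, 0.537 with an estimated correlation). *dpy-2*, *dpy-4* and *dpy-5* had values of 3.44, 1.45 and 1.38. Of 21 moulting genes, which act in the replacement of the cuticle, 18 were higher (median 0.76, adjusted p = 1.47e-07 by camera, 0.537 with an estimated correlation), with 2.54 for *mlt-8*, 1.25 for *mlt-9* and 4.43 for *mlt-11*. All 46 tested sperm genes were higher (median 0.45, adjusted p = 1.79e-05), as were 24 of 26 neuron markers (0.23), 14 of 15 body wall muscle markers (0.23), 11 of 11 pharynx markers (0.39), 45 of 57 replication-dependent histones (0.14) and 67 of 73 cytosolic ribosomal protein genes (0.08). Their adjusted p with an estimated correlation was 0.749 for sperm, histone and ribosomal genes, 0.333 for neuron and 0.537 for muscle and pharynx markers. Lower were 20 of 21 oogenesis and eggshell genes (-0.21), with -0.29 for the yolk receptor gene *rme-2*, 21 of 23 maternal regulators of the early embryo (-0.19), 24 of 25 DNA replication and cell cycle genes (-0.19) and 12 of 14 P granule genes (-0.14), each with an adjusted p = 0.537 with an estimated correlation. Camera with its preset correlation called these 12 of 25 lists. With an estimated correlation it called 0 (smallest adjusted p = 0.333 with an estimated correlation, for the neuron markers), and 0 members passed over all genes or adjusted over the list alone. Mutant replicate 1 alone held 211 CPM of *mlt-11*, 27.5 CPM of *mlt-8* and 29.5 CPM of *dpy-2*, against at most 10.4, 6.63 and 3.15 CPM elsewhere. Relative to the stage mean, its median log2 CPM was 0.88 for moulting genes, the highest of the stage. For collagens it was -1.148, the lowest of the mutant libraries, and *dpy-2* does not stand for that list. Collagens were highest in mutant replicate 4 (1.935), so the collagen and moulting shifts rest on different libraries. Wild-type replicate 2 stood apart in RNA composition, with 2.71% of counts from signal recognition particle RNA (3.98% to 5.76% in the other young adult libraries), 0.524% from mitochondrial genes (at most 0.278%) and a TMM factor of 1.27 (0.837 to 1.15). Median values moved by more than 1.5 times without single libraries, and calls were lost where marked. Without mutant replicate 1 the medians were 0.20 for moulting genes, -0.19 for P granule genes and -0.11 for histones (all lost), 0.74 for sperm and 0.15 for ribosomal genes. Without mutant replicate 2 they were 0.18 for muscle, 0.09 for histones and 0.02 for ribosomal genes (all lost), -0.32 for oogenesis, -0.27 for P granule and -0.31 for maternal genes and 0.61 for pharynx. Without mutant replicate 3 they were -0.12 for maternal genes and 0.27 for histones. Without mutant replicate 4 they were -0.08 for sperm, -0.10 for P granule, -0.03 for pharynx and 0.03 for ribosomal genes (all lost), 0.12 for collagens, -0.13 for oogenesis, -0.11 for maternal, 0.13 for muscle and -0.08 for DNA replication genes. Without wild-type replicate 1 they were -0.09 for P granule and -0.12 for maternal genes, 0.40 for histones and 0.18 for ribosomal genes. Without wild-type replicate 2 they were 0.17 for sperm, 0.07 for muscle and 0.31 for pharynx (all lost), and histones (-0.10) and ribosomal genes (-0.09) were called lower. Without wild-type replicate 3 they were -0.16 for P granule genes (lost), 0.77 for sperm, -0.12 for oogenesis genes, 1.56 for collagens, 0.41 for muscle and 0.25 for ribosomal genes. Without wild-type replicate 4 they were 0.07 for histones and 0.03 for ribosomal genes (both lost) and 0.15 for muscle.

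In L4 larvae no gene passed edgeR's test either. Of 12631 genes tested, 0 passed and 76 (0.602%) had an unadjusted p under 0.05 (46 higher, 30 lower). This share too is below the 0.05 expected of a calibrated test if no gene differs. DESeq2 called 0, with 166 at an unadjusted p under 0.05. The smallest p belonged to *ins-35*, an insulin-like peptide gene (2.15-fold lower; 2 ± 0.152 against 4.31 ± 0.668 CPM), F35F10.5 (log2 fold change -1.06), Y102A5C.36 (1.20; 4.24 ± 0.574 against 1.85 ± 0.426 CPM), the pseudogene WBGene00014955 (0.78; 11.4 ± 0.999 against 6.58 ± 0.867 CPM) and Y73B6BL.12 (2.16; 1.32 ± 0.705 against 0.287 ± 0.00495 CPM), none of which passed. For 5635 genes (44.6%) the interval lay within 2-fold of no change, and on simulated counts the test recovered 43.5% of genes changed 4-fold and 0% of those changed 2-fold.

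In mutant L4 larvae histone, ribosomal protein and sperm genes had higher medians and detoxification genes a lower one, in calls lost with an estimated correlation (adjusted p = 0.796, 0.846, 0.892 and 0.796 with an estimated correlation). Of 58 replication-dependent histones 55 were higher (median 0.32, adjusted p = 2.96e-09 by camera, 0.796 with an estimated correlation), as were 67 of 72 ribosomal protein genes (0.20), 40 of 41 sperm genes (0.60), 12 of 15 body wall muscle markers (0.34) and 8 of 10 P granule genes (0.31). The adjusted p of muscle and P granule genes was 0.796 with an estimated correlation. *rla-0*, *rla-1* and *rla-2*, genes of the ribosomal stalk, had values of 0.37, 0.51 and 0.63. Lower were 98 of 134 detoxification genes (-0.22), with -0.15 for *gcs-1*, and 9 of 10 genes of the intracellular pathogen response (-0.41), with -0.45 for *skr-3* and -1.18 for *cul-6* (adjusted p = 0.796 for both lists with an estimated correlation). These 7 of 24 lists were called with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.796 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Mutant replicates 1 and 2 stood apart in RNA composition, with 11.5% and 12.1% of counts from signal recognition particle RNA (4.86% to 6.62% in the other L4 libraries), 18.3% and 23.2% from ribosomal RNA, and TMM factors of 0.704 and 0.734 (0.905 to 1.35 in the others). Without mutant replicate 1 the medians were 0.09 for sperm, 0.14 for P granule and 0.04 for ribosomal genes (all lost) and 0.20 for histones. Without mutant replicate 2 they were 0.41 for sperm, 0.19 for P granule and -0.24 for pathogen response genes (all lost), 0.22 for muscle and -0.11 for detoxification. Without mutant replicate 3 they were 1.17, 0.55, -0.73, -0.39, 0.58 and 0.37 for sperm, P granule, pathogen response, detoxification, histone and ribosomal genes. Without wild-type replicate 1 they were 1.75, 0.59, 0.55, 0.75 and 0.52 for sperm, P granule, muscle, histone and ribosomal genes. Without wild-type replicate 2 they were 0.20, 0.18, -0.36 and 0.03 for P granule, muscle, pathogen response and ribosomal genes (all lost) and 0.15 for histones. Without wild-type replicate 3 they were 0.12 for sperm and 0.24 for P granule genes (both lost). The 7 lists became 12 without wild-type replicate 1, 4 without mutant replicate 1 and 3 without wild-type replicate 2.

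In mixed embryos *gpap-1* had the smallest adjusted p (0.0647 by edgeR) and missed the threshold. Of 12287 genes tested, 0 passed and 85 (0.692%) had an unadjusted p under 0.05 (26 higher, 59 lower). This share too is below the 0.05 expected of a calibrated test if no gene differs. DESeq2 called 1, *gpap-1*. Without mutant replicate 3 *gpap-1* passed edgeR's test as well (adjusted p = 0.0342, from 6.34e-08 to 1 over the alternatives). After *gpap-1* and *cls-3* came *gst-12*, a glutathione S-transferase gene (log2 fold change -1.33; 0.364 ± 0.116 against 0.897 ± 0.0749 CPM), WBGene00014955 (1.03; 4.55 ± 1.19 against 2.23 ± 0.708 CPM) and the noncoding RNA M163.16 (-1.34; 1.44 ± 0.446 against 3.71 ± 1.97 CPM), none of which passed. For 10982 genes (89.4%) the interval lay within 2-fold of no change, and on simulated counts the test recovered 100% of genes changed 4-fold, 67.2% of those changed 2-fold and 12.1% of those changed 1.5-fold.

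Median list shifts in embryos were small. Of 67 replication-dependent histones 54 were higher (median 0.18, adjusted p = 2.04e-07 by camera, 0.94 with an estimated correlation), as were 18 of 19 oogenesis and eggshell genes (0.13) and 20 of 23 maternal regulators (0.12), with 0.30, 0.12 and 0.18 for *mex-1*, *mex-3* and *mex-5*. Both of the latter lists had an adjusted p = 0.94 with an estimated correlation. Lower were 60 of 91 cuticle collagens (-0.07), 73 of 117 detoxification genes (-0.12), 12 of 15 intestine markers (-0.09) and 14 of 15 body wall muscle markers (-0.09), with -0.11 for the myosin gene *unc-54* (adjusted p = 0.269 for intestine and 0.94 for the other lists with an estimated correlation). These 7 of 23 lists were called with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.269 with an estimated correlation, for the intestine markers), and 0 members passed over all genes or adjusted over the list alone. For the collagens the mean was -0.32 and for the intestine markers -0.31, where the lowest member, *cpr-1* (-2.02), held 39.4 CPM in wild-type replicate 1 against at most 6.73 CPM elsewhere. Single libraries moved these values and calls. Without wild-type replicate 1 only 2 lists were called, and histones (0.13), oogenesis genes (0.03), collagens (-0.01), maternal regulators (0.04), muscle (-0.06) and intestine markers (-0.07) lost their calls. Without wild-type replicate 2 the count was 12, with medians of 0.31, 0.28 and 0.29 for oogenesis genes, maternal regulators and histones. Without wild-type replicate 3 oogenesis genes (0.00), maternal regulators (0.00) and detoxification genes (-0.05) lost their calls, and collagens had -0.14 and histones 0.07. Without wild-type replicate 4 the intestine median was -0.04. Without mutant replicate 1 maternal regulators (0.09) and detoxification genes (-0.03) lost their calls, and collagens, muscle, intestine and histones had -0.16, -0.18, -0.17 and 0.06. Without mutant replicate 2 only 2 lists were called, and histones (0.10), oogenesis genes (0.12), maternal regulators (0.09), muscle (-0.02) and intestine markers (-0.04) lost their calls. Without mutant replicate 3 collagens (0.00) and muscle (-0.03) lost theirs, and oogenesis genes, maternal regulators and histones had 0.25, 0.29 and 0.40. Without mutant replicate 4 the count was 4, oogenesis genes (-0.06), maternal regulators (0.03) and muscle (-0.06) lost their calls, and detoxification genes had -0.06.

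**Figure D3:**
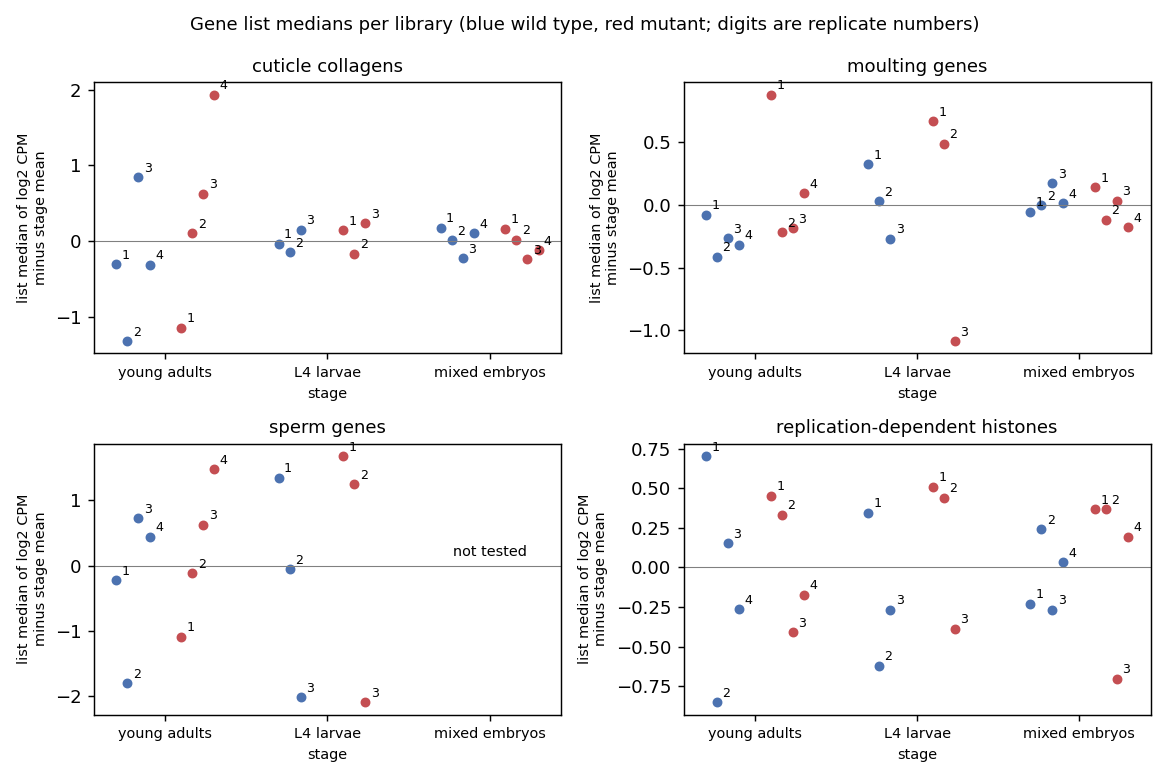
Median log2 CPM of 4 gene lists in each library, relative to the mean of its stage (blue, wild type; red, mutant; digits, replicate numbers; sperm genes were not tested in embryos). Libraries of the same genotype spread widely, as for sperm genes in L4 larvae, where values run from -2.10 to 1.68.

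The genotype effect was not shown to differ between stages for any gene. The interaction test in edgeR passed 0 of 15433 genes, with 358 at an unadjusted p under 0.05, and DESeq2's likelihood ratio test passed 0. For *cls-3*, with log2 fold changes from -2.12 to -0.57, the interaction was not significant (adjusted p = 1 by edgeR). With 0 genes called by edgeR at each stage, the overlap between stages was 0. DESeq2's calls shared 1 gene that was lower in young adults and embryos, *gpap-1*, against 9.41e-05 expected among 21246 genes (Fisher's exact test, one-sided p = 9.41e-05). With 2 and 1 calls this p depends on the number of genes counted, and the filtered main fits shared only 10350 genes.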

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

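The tests of developmental delay, linked DNA and copy number, and the fit over the 3 stages together, were chosen after the result was seen. Each group of replicates was searched for a value standing apart from the rest. Of 78 groups searched, 6 had such a value, where about 3.9 are expected by chance. The neuron list median of wild-type young adult replicate 2 was -0.421 against -0.056 to -0.027, and the intestine list median of wild-type embryo replicate 4 was 0.096 against -0.020 to -0.003. In mutant embryos *gst-12* stood at 0.193 CPM in replicate 3 against 0.401 to 0.443, M163.16 at 2.1 CPM in replicate 2 against 1.16 to 1.30, the muscle list median at 0.290 in replicate 1 against -0.177 to -0.149, and the histone list median at -0.703 in replicate 3 against 0.194 to 0.369.

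Regrouping the libraries shows what counts arise without the genotype. A real count of 0 genes is reached by every split whatever the data, so 35 of 35 in young adults (highest other 13), 35 of 35 in embryos (highest other 712) and 100 of 100 relabellings for the interaction (highest other 3838) test nothing. For lists 16 of 35 splits gave at least the real count in young adults (12, highest other 19) and 24 of 35 in embryos (7, highest other 15), so chance is not excluded for these counts. In L4 larvae the 10 splits are too few to exclude chance (genes, real 0 and highest other 5624, reached by 10; lists, real 7 and highest other 11, reached by 6). The median of the other splits was 0 genes at each stage, and over 100 genes were called in 1 of 9 other splits of L4 larvae, 1 of 34 of embryos and 0 of 34 of young adults. Genes at an unadjusted p under 0.05 numbered 145, 76 and 85 in the real splits of young adults, L4 larvae and embryos. The medians of the other splits were higher, at 554, 115 and 414.5. For the interaction 8 of 99 relabellings called over 100 genes, with a median of 0. In L4 larvae the split with 5624 calls set wild-type replicate 1 and mutant replicates 1 and 2 against the other libraries. These libraries scored 52, 53.8 and 34 on the first principal component of the group-centred values, against -87.9 to -10.1 in the others. That component held 77.7% of the variance, so this split follows a spread that crosses genotypes. What causes that spread, and what sets the other splits with far more calls than the real one apart, was not tested.

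*gpap-1* and *cls-3* were lower in the mutant at every stage. A chance separation is argued against by 2 such genes where 0.2 were expected, although 8 of 100 relabellings gave at least the 1 gene called over the 3 stages (highest other 665), so chance is not excluded for that count. A delay of mutant young adults toward the L4 stage could lower *cls-3*, but the 2636 other genes that are at least as much higher in wild-type young adults than L4 larvae had a median of -0.19 (quartiles -0.28 and -0.09) against -2.12 for *cls-3*. This argues against a delay as the source of the whole fall in *cls-3*. Both quartiles lie below 0, so a smaller delay is not excluded. The stages also differ in growth temperature, so these genes are not markers of stage alone. Of the lists that camera called in young adults with its preset correlation, all but sperm genes and histones shifted toward the wild-type L4 level. Those calls were lost with an estimated correlation, and whether a delay underlies the shifts was not tested. DNA linked to an edited locus is argued against by position, since 0 of the 2 genes lie on chromosomes II or X. A difference in strain background elsewhere and an effect of the altered Argonautes both stay open.

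Y102A5C.36 and the pseudogenes WBGene00014954 and WBGene00014955, neighbours on chromosome V (16926922 to 16930063), had log2 fold changes of 0.79, 0.67 and 0.64 over the 3 stages, and none passed edgeR's test (adjusted p = 0.153, 0.999 and 0.868). With DESeq2 Y102A5C.36 passed (adjusted p = 0.0245). By edgeR its adjusted p ran from 0.0694 to 0.513 with single libraries left out. A copy number change reaching 25 kb to either side could raise all 3, but the 7 other tested genes there had a median of -0.09 against 0.67, which argues against it. On the side of higher coordinates the only tested gene was *clec-238*, which starts at 16951804. A shorter change over these 3 genes, one that also reaches toward *clec-238*, and chance, which was not tested, stay open.

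Libraries of the same group spread widely in young adults and L4 larvae. A gene length bias, as from RNA breakdown, may contribute in young adults, where the loadings of the first component correlated with gene length (rho = -0.34 over 12561 genes, which are not independent). On that component sperm genes and cuticle collagens had the highest median loadings of the tested lists. Length was not separated from gene family, so the correlation alone does not show RNA breakdown. Length in L4 larvae (rho = -0.20 over 12631 genes) and developmental time in L4 larvae (0.13 over 12320 genes) and young adults (-0.22 over 12394 genes) lay between the bounds set for no relation and for a cause, so these values decide nothing. In L4 larvae sperm and moulting genes had median loadings of the same sign. From wild-type L4 larvae to young adults they moved in opposite directions (median log2 fold changes 2.43 and -4.71). Such a correlation can therefore miss a timing difference within the L4 stage. What drives the spread stays open.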

How the results depend on the processing

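The principal component covariate, the single effect over the 3 stages and the removal of both first embryo libraries are tests chosen after the result was seen. In young adults DESeq2 called 2 genes where edgeR called 0. In L4 larvae the principal component covariate called 2 (*clec-230* and *cls-3*). In embryos DESeq2 called 1, the principal component covariate 1, and leaving out single libraries gave 0 to 1, *gpap-1* each time. Without a low-count filter edgeR called 94 genes in embryos (15 higher, 79 lower). There the prior degrees of freedom became infinite, against 7.15 with the filter, and in 86 of the 94 genes 1 library stood at least 2-fold over the next. Wild-type replicate 1 was the highest library in 66 of these genes and mutant replicate 1 in 5. The overlap between stages was 1 gene with DESeq2. Over the 3 stages together edgeR called 2 genes with DESeq2 size factors, 2 without the filter, and 1 to 2 when single libraries were left out, the added gene being *cls-3*. DESeq2 called 3 there, adding Y102A5C.36.

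With an estimated correlation 0 lists were called in young adults, L4 larvae and embryos, and with fry 0. Leaving out single libraries gave 10 to 17 lists in young adults, 3 to 12 in L4 larvae (12 without wild-type replicate 1) and 2 to 12 in embryos. Without wild-type replicate 2 the 12 young adult calls split into 3 higher and 9 lower. Without both first embryo libraries 0 genes and 7 lists were called (1 higher, 6 lower).

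Signs of genes, or camera's direction for lists, reversed when single libraries were left out, with ranges of -0.02 to 0.43 for *alg-1*, -0.01 to 0.43 for *alg-2*, -0.41 to 2.73 for *hbl-1*, -0.08 to 0.77 for sperm genes, -0.11 to 0.40 for histones and -0.09 to 0.25 for ribosomal genes in young adults. The median of pharynx markers there ranged from -0.03 to 0.61 with no reversal of camera's direction. In L4 larvae sperm genes ranged from 0.09 to 1.75. In embryos *alg-1* ranged from -0.20 to 0.08, oogenesis genes from -0.06 to 0.31 and maternal regulators from 0.00 to 0.29. The cause was not tested.

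With the replicate number as a block edgeR called 1 gene in embryos, *gpap-1*, the list counts were 12, 7 and 7, *hbl-1* in young adults had 0.69, the ribosomal list in young adults (0.14) lost its call, and FOXO targets in young adults (median -0.20, adjusted p = 0.0485, and 0.204 without the block) were called lower. The block changed no other call. Deviations of same-numbered libraries correlated above 0.1 in 3 of 4 pairs of young adults, 2 of 3 of L4 larvae and 3 of 4 of embryos. The correlations ran from 0.0792 to 0.581 in young adults, -0.0557 to 0.792 in L4 larvae and -0.0988 to 0.615 in embryos. Of the libraries 5 of 8, 4 of 6 and 3 of 8 correlated best with their own number, so not every pair or library goes with its number. Mutant and wild-type libraries of the same stage and number carry consecutive sample codes in the labels. The labels name no shared batch, so the numbers were not used as pairs in the main fits. A batch shared within numbers stays open. Over all alternatives, those above included, 655 values of genes and lists kept their direction and side of the threshold, 98 lost a call, 14 gained one and 15 reversed (lists by camera's direction), while 112 counts stayed within 1.5 times and 26 moved.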

Other observations

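The comparisons between wild-type stages and the lists by biotype or chromosome, with their leave-one-out values, were tests chosen after the result was seen. Wild-type young adults and L4 larvae, grown at 25 °C and 20 °C, differed at 7227 of 13374 genes (3519 higher and 3708 lower in young adults, adjusted p under 0.05 by edgeR). All 5 tested vitellogenins, the yolk protein genes, rose in young adults, as did 19 of 21 oogenesis and eggshell genes (median 26.1-fold), 20 of 23 maternal regulators (8.93-fold) and 23 of 25 DNA replication genes (3.87-fold). Lower were 20 of 22 moulting genes (median 26.1-fold), 84 of 126 collagens (19.3-fold), 15 of 15 muscle markers (2.85-fold) and 24 of 26 neuron markers (2.93-fold). *alg-1* fell by 1.73 on the log2 scale and *alg-5*, a further microRNA Argonaute gene, rose by 2.58, while *alg-2* had -0.29 and did not pass. *rme-2* rose by 5.51 and *lin-41* by 2.98, *lin-14* fell by 1.35 and *hbl-1* by 1.26. Stage and temperature cannot be told apart here. Leaving out single libraries gave 5613 to 7422 genes.

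Wild-type embryos differed from young adults at 9850 of 13470 genes (4685 higher, 5165 lower), and 9386 to 10417 with single libraries left out. All 19 zygotic lineage regulators rose (median 13.9-fold), as did 19 of 23 moulting genes (54.8-fold) and 17 of 24 genes of the microRNA target list (3.42-fold). All 44 sperm genes fell (435-fold), as did 20 of 21 oogenesis genes (10.8-fold). *alg-1* rose by 2.92 and *alg-2* by 2.79, *alg-5* fell by 1.84, and *hbl-1* rose by 6.67. Of 35 splits, 1 (the real one) reached each of these counts, 7227 in the first comparison and 9850 in this one, with 0 as the highest other, so chance is excluded at the level 35 splits allow.

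In embryos all 11 tested mitochondrial protein genes were higher in the mutant (median 0.39, p = 7.21e-12 by camera, 0.0386 with an estimated correlation, neither adjusted), and 0 of them passed singly. The share of counts from mitochondrial genes overlapped between genotypes, at 0.148% to 0.271% in the mutant and 0.0705% to 0.269% in wild type, lowest in wild-type replicate 2. Leaving out single libraries kept the call with the preset correlation (p = 1.06e-29 to 0.00143), with medians from 0.19 without wild-type replicate 2 to 0.83 without wild-type replicate 4. With an estimated correlation p exceeded 0.05 without wild-type replicate 1 (median 0.33, p = 0.143), wild-type replicate 2 (p = 0.241), mutant replicate 1 (0.22, p = 0.187) or mutant replicate 3 (0.53, p = 0.0763). In young adults 7 of 11 were lower (median -0.15, p = 0.905 by camera) and in L4 larvae 9 of 12 higher (0.16, p = 0.0928 by camera, 0.558 with an estimated correlation). Young adult medians ran from -0.32 without wild-type replicate 1 to 0.34 without wild-type replicate 2. In the latter 11 of 12 were higher (p = 0.0115 by camera, 0.393 with an estimated correlation). Without mutant replicate 1 the median was 0.01 (p = 0.0274 by camera, 0.282 with an estimated correlation). L4 medians ran from 0.00 without wild-type replicate 1 to 0.58 without wild-type replicate 2 (p = 4.04e-08 by camera, 0.112 with an estimated correlation). MicroRNA genes by biotype, of which 261 are annotated, had medians of -0.17 over 5 tested in young adults (p = 0.854 by camera), 0.52 over 10 in L4 larvae (p = 0.197) and 0.12 over 17 in embryos (p = 0.0104, 0.227 with an estimated correlation). The libraries are of total RNA, and whether these counts come from mature microRNAs was not tested, so they do not give microRNA levels. Leaving out single libraries gave medians of -0.20 to 0.06 in young adults and 0.33 to 0.78 in L4 larvae. In embryos the preset p exceeded 0.05 without wild-type replicate 1 (median 0.10), wild-type replicate 2 (0.18) or mutant replicate 4 (-0.01), and the medians without mutant replicates 2 and 3 and wild-type replicates 3 and 4 were 0.24, 0.23, 0.23 and 0.26.

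Separation of every mutant from every wild-type library occurred for 153 genes in young adults of 12561 (chance share 2.86%), 491 in L4 larvae (3.89%, chance share 10%) and 67 in embryos (0.545%, chance share 2.86%), below chance at each stage. Single embryo libraries stood apart. Wild-type replicate 1 held 42.4 CPM of *dpy-13* against at most 2.04 CPM elsewhere, 27.9 against 6.52 CPM of *col-147*, 39.4 against 6.73 CPM of *cpr-1* and 74.6 against 11.5 CPM of *far-2*. Mutant replicate 1 held 74200 CPM of *rrn-3.1* against at most 9700 and 7700 CPM of F31C3.14 against at most 78.4. The cause was not tested.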
